A study of Arabidopsis thaliana with 6 samples.

How the data were processed

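RNA was measured in whole seedlings of Arabidopsis thaliana, ecotype Col-0, in 6 samples with 1 Affymetrix array each. Per the labels, total RNA was extracted with Trizol and biotin-labelled cRNA was prepared by the standard Affymetrix protocol. Per the labels, seedlings grew at 23 °C on solid medium, and the heat groups received 37 °C for 30 min. The groups follow the labels: 3 control samples and 3 heat samples, all under light. The labels also give a different age to each array, from 10 to 15 days. The age rises with the order of the arrays, so it was used only as an alternative covariate. Whether the samples of a group came from separately grown seedlings is not stated in the labels, so p-values measure the spread between samples whose independence is not given.

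The deposited value table holds log2 levels, 1 column per array. The submitters' processing notes name RMA, a method that subtracts background, gives all arrays the same distribution of probe intensities and summarises each probe set on the log2 scale. The version of that tool and the release of the array annotation are not given in the sources used here. The values were used as deposited and not normalized again. The authors' annotated table repeats the log2 levels: all 136860 cells equal those of the value table. The authors' table also holds a linear ratio of control over heat for each pair of arrays with the same replicate number, and the log2 of each ratio was within 0.0001 of the difference between the arrays. Its 5 columns for p-values or F statistics hold no values, so all tests come from the fit described here. Array quartiles were near equal, which this type of normalization imposes, so a change in the total amount of messenger RNA would not show in these values.

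Of 22810 probe sets, the 64 control probe sets were left out of the tests and 22746 were tested. By the gene identifier in the authors' annotation, 20661 probe sets name a single gene, 819 name several and 1266 name none. Of the single-gene probe sets, 20540 matched a locus in the RefSeq gene table of assembly TAIR10.1 and 121 did not. Those 121 were tested as probe sets but took no part in counts per gene, lists, named genes or title words. That table was used for gene names and for the order of neighbouring loci, and no probe sequence or genome sequence was analysed here. Where a gene had more than 1 single-gene probe set, as 224 genes did, the 1 with the highest mean over the 6 arrays stood for the gene.

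The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group as the only factor, 2-sided moderated test, 4 residual and 2.65 prior degrees of freedom), with Benjamini-Hochberg adjustment over all 22746 probe sets. Counts were taken at an adjusted p under 0.05 and an absolute log2 change of at least 1. Errors of changes are limma standard errors, and errors of levels are standard deviations of 3 arrays. Exact permutation of 3 against 3 arrays cannot give a p below 0.1, and the limma test relies instead on the spread estimated over all probe sets. Lists were tested with camera at a preset correlation of 0.01 between genes, adjusted over the 21 lists, and also with an estimated correlation, under which 2 of the 7 called lists, both of chaperones, were called. The rotation test fry, which asks whether a list moves on balance in 1 direction and does not compare it with other genes, called 12 lists. The lists were written from general knowledge, and members were counted at an adjusted p under 0.05 over all probe sets and adjusted over the list alone. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

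The lists, the tests, the thresholds, the rule for named genes and the first set of alternative settings were fixed before the data were examined. The rule named the 10 genes with the largest rises and the 10 with the largest falls among those that passed and whose groups did not overlap, up to 4 members of each list with the largest change among those that passed, and always HSFA1A, HSFA1B, HSFA1D, HSFA2, HSP101, PHYB, PIF4 and HY5. The chromosome 2 genes, HSFA1E, HSFA8, HSFA4C, HSFC1, PDIL1-1, BZIP60, BIP3, PHYC, CRY1, CRY2 and PHOT1 were chosen after their values were seen. The same holds for BZIP28, PHYA, PHYD, PHYE, UVR8, PHOT2 and WRKY40. So were the genes named only in the closing section apart from their lists. That set held quantile normalization, centring of each array on its median, leaving out the dimmest 25% of probe sets, a prior variance with a trend, array weights, a replicate block, the labelled age as a covariate, 1 probe set per gene, other fold minimums, other list tests, the mean over the probe sets of a gene, and leaving out each array in turn. Scaling to the 24 Bacillus control probe sets, tests with the spread of each probe set alone (no moderation), a scan of the words in gene titles and the description of the chromosome 2 genes were added after seeing the data.

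The fit was tested on simulated data with the spread of each probe set in the real arrays. Simulated probe sets varied independently of each other, with the same spread in both groups. Of 100 probe sets given a log2 change of 1, 72% were recovered, and of 100 given a change of 2, 94% were. In that simulation 4 unchanged probe sets were called, 2.35% of all calls. A shift of 0.5 put into the circadian clock list was called with an adjusted p of 3.53e-17, and 0 other lists were called. Since simulated genes did not vary together, neither this result nor the share of false calls covers genes that do. Left out were the control probe sets, except where they are named, and the dark-treated groups of the series text, which were not analysed here.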

Results

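RNA levels were measured in whole seedlings of Arabidopsis thaliana, ecotype Col-0, on 6 Affymetrix expression arrays with 1 sample each. The control group held 3 samples kept under light at the growth temperature of 23 °C, and the heat group held 3 samples given 37 °C for 30 min under light. The arrays carried 22810 probe sets, and the 22746 left without the control probe sets were tested. Of the tested probe sets 20661 name a single gene, and the 20540 of them that matched a locus cover 20310 genes. Array medians lay between 4.39 and 4.53 on the log2 scale. An array gives no read count, so the number of arrays limits the precision. The heat arrays lay close together, with a standard deviation of 0.19 to 0.28 for the difference between any pair of them, against 0.36 to 0.55 between control arrays. The labels give each array its own age, from 10 to 15 days in the order of the arrays. The series text instead gives 10 days for all seedlings, so the labelled ages may not be real ages. That text also names dark-treated groups, which were not analysed here.

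The comparison of heat with control seedlings addressed the heat stress response of the transcriptome under light. Heat raised the genes of the heat shock response by the largest amounts. HSP17.7-CII (AT5G12030), a cytosolic small heat shock protein that holds unfolding proteins in solution, rose from 4.02 ± 0.66 to 13.78 ± 0.04 (log2 level, mean ± SD, n = 3 each). HSFA2 (AT2G26150), the transcription factor that sustains the heat shock response, rose from 4.90 ± 2.08 to 12.86 ± 0.05. HSP101 (AT1G74310), the disaggregase needed for acquired heat tolerance, rose from 5.97 ± 1.95 to 13.74 ± 0.08. Among genes that passed the test, the largest fall was in ERF6 (AT4G17490), a stress-responsive ethylene response factor, from 8.81 ± 1.88 to 4.06 ± 0.17, and the expansin gene EXPA1 (AT1G69530), whose product loosens cell walls, fell from 9.62 ± 1.02 to 5.66 ± 0.08.

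Of the 22746 probe sets, 637 rose and 906 fell at an adjusted p under 0.05 and a change of at least 2-fold, together 6.78% of those tested. Without the fold minimum, 1778 rose and 2614 fell. Rises were the larger changes: 106 probe sets rose at least 16-fold and 4 fell by as much, and 47 rose at least 64-fold. At 1 probe set per gene, 580 genes rose and 857 fell by at least 2-fold. All heat arrays lay above, or all below, all control arrays for 38.8% of probe sets, where chance gives 10%. With the labelled age as a covariate, which runs from the control to the heat arrays, the counts were 359 higher and 227 lower. Of the 85 genes that passed among those named by the fixed rule, 54 were not called with that covariate. Because the labelled age runs with the groups, it also widens the error, so a lost call alone does not show a smaller change. Of those 54 genes, 25 also moved by over 1.5 times, 15 of them to a smaller change. For these 25 genes the value is given with the gene. After scaling the arrays to the Bacillus control RNAs added to the samples, an alternative chosen after seeing the data, they were 462 higher and 2906 lower, and the median change of all probe sets moved from 0.02 to -0.46. That fit estimated 68.8 prior degrees of freedom, against 2.65 without the scaling, and so gave almost all probe sets the same error. Its p-values take little account of how far a single gene varied. With the spread of each probe set alone, the counts were 325 higher and 1205 lower after that scaling and 541 and 551 without it. Centring each array on its median moved that value to 0.12. All changes given here are therefore relative to the bulk of the transcripts on the array. Where the call on a gene named by the rule was lost when single arrays were left out in turn, those arrays are named with the highest adjusted p reached. Leaving out an array also lowers the residual degrees of freedom and changes the estimated spread. Such a loss alone therefore does not show that the change rests on the array left out.

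Small heat shock proteins bind denatured proteins in the cytosol, the organelles and the endoplasmic reticulum. Of 16 measured, 14 rose and 0 fell, as they did adjusted over the list alone, and the list had a median change of 8.94 (camera adjusted p = 3.05e-22; adjusted p = 0.0573 with an estimated correlation). HSP17.6C-CI (AT1G53540) rose by 9.68 ± 0.10 (log2, ± SE; adjusted p = 4.94e-08) and HSP17.6-CII by 9.62 ± 0.10 (adjusted p = 4.94e-08). The organelle forms rose by 9.36 ± 0.13 for HSP26.5 (adjusted p = 1.96e-07), 9.07 ± 0.21 for the mitochondrial HSP23.6 (adjusted p = 1.54e-06), 9.07 ± 0.10 for HSP22.0 of the endoplasmic reticulum (adjusted p = 8.3e-08) and 8.98 ± 0.09 for the plastid HSP21 (adjusted p = 4.94e-08). HSP17.4 rose by 9.25 ± 0.14 and HSP18.1-CI by 8.89 ± 0.15. Mean control levels ran from 3.03 for HSP26.5 to 4.62 for HSP17.4 among these genes, with array minima of 2.53 to 2.66 and array medians of 4.39 to 4.53. The share of background in these levels was not measured, so the order of the rises is not a ranking.

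The HSP70, HSP90 and HSP100 chaperones, which fold proteins and take aggregates apart, rose in 17 of 18 measured genes and fell in 0, with the same counts adjusted over the list alone. Their median change was 3.64 (camera adjusted p = 2.58e-19; adjusted p = 0.0424 with an estimated correlation). HSP70B (AT1G16030) rose by 9.08 ± 0.07 (adjusted p = 3.67e-08), HSP70T-2 by 8.06 ± 0.18 (adjusted p = 1.31e-06), HSP101 by 7.78 ± 0.88 (adjusted p = 0.00158) and HSP90.1 (AT5G52640) by 7.52 ± 0.86 (adjusted p = 0.0017). Of 20 co-chaperones, chaperonins and heat tolerance factors, 18 rose and 0 fell, or 19 and 0 adjusted over the list alone, with a median of 3.15 (camera adjusted p = 7.88e-18; adjusted p = 0.0424 with an estimated correlation). In this list the immunophilin ROF2 rose by 7.97 ± 0.86 (adjusted p = 0.00133), the co-chaperone BAG6 by 7.89 ± 0.75 (adjusted p = 0.000748), the chaperone organizer HOP3 by 7.76 ± 0.38 (adjusted p = 4.13e-05) and the coactivator MBF1C by 7.12 ± 0.89 (adjusted p = 0.00246). ROF2, BAG6 and MBF1C were not called with the age covariate. Their changes were then 5.60 (adjusted p = 0.162), 5.90 (adjusted p = 0.114) and 4.2 (adjusted p = 0.234).

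Heat shock factors are the transcription factors that switch these genes on. Of 20 measured, 9 rose and 3 fell, with the same counts adjusted over the list alone; the list median was 0.03 and its mean 1.42, and after scaling to the Bacillus controls the median was -0.45. The list was called as higher after heat (camera adjusted p = 0.0352; adjusted p = 0.451 with an estimated correlation), and without control replicate 1 it was not (adjusted p = 0.101). HSFA2 rose by 7.95 ± 0.93 (adjusted p = 0.00188), and rises were also measured in HSFA7B with 6.92 ± 0.15 (adjusted p = 9.37e-07), HSFA7A with 6.60 ± 0.50 (adjusted p = 0.000273) and the repressor-type HSFB2B with 3.76 ± 0.38 (adjusted p = 0.000956). Among the A1 factors, the master regulators that start the response, HSFA1D rose by 1.24 ± 0.13 (adjusted p = 0.00129) and HSFA1E by 0.79 ± 0.18 (adjusted p = 0.0232). The call on HSFA1E was lost without control replicate 1 or 2 or heat replicate 1 (up to 0.0785), with the age covariate (adjusted p = 0.298) and after scaling to the Bacillus controls (0.31, adjusted p = 0.244). HSFA1A differed by -0.02 ± 0.17 (adjusted p = 0.961) and HSFA1B by -0.11 ± 0.13 (adjusted p = 0.599), neither past the threshold. HSFA1B was at -0.59 after scaling to the Bacillus controls, called in that fit (adjusted p = 0.0361) and not with its own spread (adjusted p = 0.101). The members that fell were HSFA8, HSFA4C and HSFC1, and each call was lost in 4 of the fits that left out 1 array (adjusted p up to 0.0788, 0.151 and 0.0962). They were at -3.79 (adjusted p = 0.0411), -1.88 (adjusted p = 0.105) and -1.54 (adjusted p = 0.293) with the age covariate.

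The control arrays were not alike for these genes. In control arrays 1, 2 and 3 the level of HSFA2 was 3.69, 3.72 and 7.30, that of HSP101 was 4.82, 4.87 and 8.22, and that of HSP90.1 was 4.80, 4.80 and 8.13. The level of HSP70B was 4.62, 4.61 and 4.55. Of the 47 probe sets that rose at least 64-fold, 21 were over 2-fold higher in control array 3 than in the mean of the other control arrays. Without control replicate 3, 627 probe sets rose and 998 fell. With the labelled age as a covariate, the changes of HSFA2 (adjusted p = 0.202), HSP101 (adjusted p = 0.179) and HSP90.1 (adjusted p = 0.189) were 5.25, 5.22 and 5.01 and were not called.

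**Figure D1:**
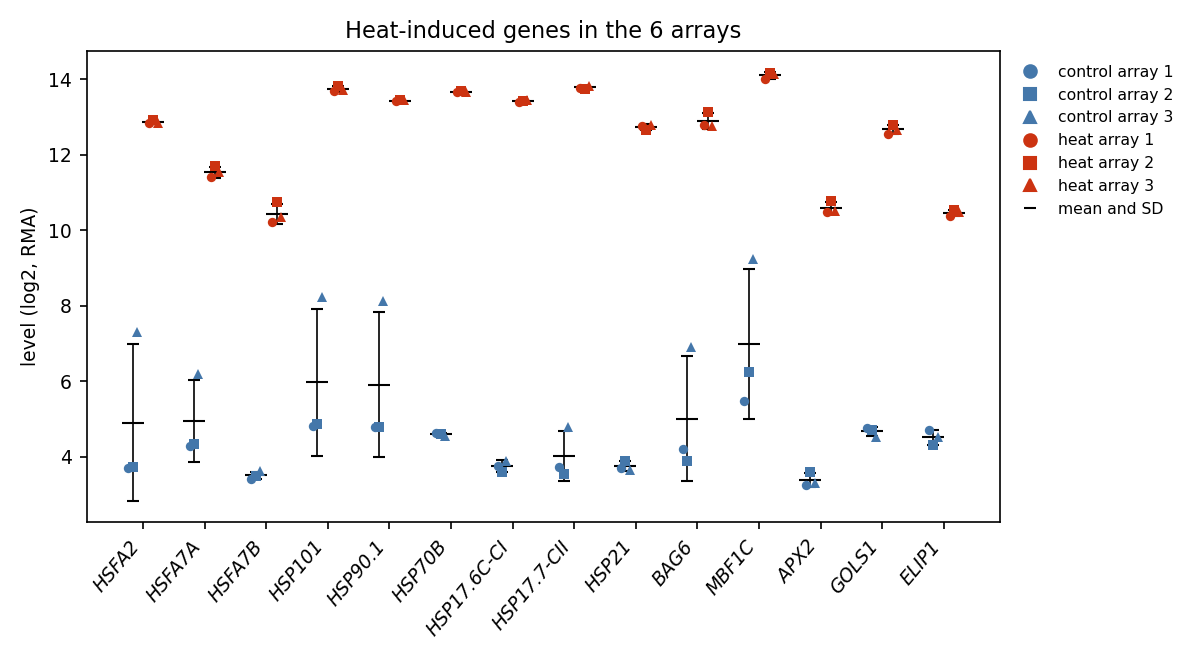
Levels of 14 heat-induced genes in the 6 arrays. The vertical axis is the RMA level on the log2 scale, points are arrays, and black bars give the mean and standard deviation of 3 arrays. Heat arrays lie above control arrays for each gene. Control array 3 lies clearly above the other control arrays for HSFA2, HSFA7A, HSP101, HSP90.1, HSP17.7-CII, BAG6 and MBF1C.

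Of 14 endoplasmic reticulum chaperones and unfolded protein response genes, 7 rose and 1 fell, or 7 and 2 adjusted over the list alone. Their median was 0.56 (camera adjusted p = 0.012, or 0.546 with an estimated correlation), and 0.08 after scaling to the Bacillus controls. The co-chaperone ERDJ3A rose by 6.74 ± 0.17 (adjusted p = 2.53e-06), the lectin chaperone CNX1 by 1.83 ± 0.16 (adjusted p = 0.000459), and ERDJ3B and SDF2 each by 1.53. PDIL1-1 fell by 0.43 (adjusted p = 0.0467). BZIP28 rose by 1.44 (adjusted p = 0.0261). BZIP60 (-0.67, adjusted p = 0.462) and BIP3 (0.0, adjusted p = 0.999) were not called. BZIP60 lay at 7.07, 8.14 and 9.51 in control arrays 1, 2 and 3, and BIP3 at a low level of 3.03 in both groups. Galactinol synthases make the precursor of raffinose, a protective sugar. In the galactinol and raffinose list 4 of 5 genes rose and 0 fell, also adjusted over the list alone. The median was 0.83 (camera adjusted p = 0.000182, or 0.451 with an estimated correlation), and 0.35 after scaling to the Bacillus controls. GOLS1 (AT2G47180) rose by 8.00 ± 0.10 (adjusted p = 1.48e-07) and GOLS2 by 3.94 ± 0.30 (adjusted p = 0.000294). GOLS4 rose by 0.83 ± 0.17 (adjusted p = 0.0164) and GOLS3 by 0.56 ± 0.12 (adjusted p = 0.0199), calls that were lost without control replicate 2 for both genes (up to 0.0598 and 0.0529) and without heat replicate 3 for GOLS3. After scaling to the Bacillus controls GOLS4 differed by 0.35 (adjusted p = 0.193) and GOLS3 by 0.08 (adjusted p = 0.751).

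Of 21 antioxidant enzymes and oxidative stress regulators, 5 rose and 2 fell, or 9 and 2 adjusted over the list alone. The median of 0.23, which became -0.24 after scaling to the Bacillus controls, was not called by camera (adjusted p = 0.087). APX2 (AT3G09640), a cytosolic ascorbate peroxidase, rose by 7.22 ± 0.13 (adjusted p = 5.56e-07), the glutathione transferase GSTU19 by 1.16 ± 0.10 (adjusted p = 0.000475), and the copper/zinc superoxide dismutase CSD3 by 0.73 ± 0.10 (adjusted p = 0.00363; 0.25 after that scaling, adjusted p = 0.338). CSD2, of the plastid, fell by 1.05 ± 0.29 (adjusted p = 0.0476), a call lost without any 1 array other than control replicate 3 (up to 0.131). CSD2 was at -0.36 with the age covariate (adjusted p = 0.838). Of 12 abscisic acid and dehydration genes, 3 rose and 1 fell, also adjusted over the list alone; the median of 0.26, or -0.22 after scaling to the Bacillus controls, was not called (camera adjusted p = 0.0545), though it was without control replicate 2 (adjusted p = 0.00704) or heat replicate 1 (adjusted p = 0.0208). DREB2A (AT5G05410), a dehydration and heat response factor, rose by 4.07 ± 0.83 (adjusted p = 0.0173) with control levels of 6.10, 8.95 and 9.55, and the call was lost without any 1 of the heat replicates (adjusted p up to 0.0661). DREB2A differed by 1.53 with the age covariate and was not called (adjusted p = 0.696). Its relative DREB2B rose by 2.56 ± 0.14 (adjusted p = 7.51e-05) and the phosphatase gene ABI2 by 0.88 ± 0.14 (adjusted p = 0.00663; 0.40 after that scaling, adjusted p = 0.14), while RAB18 fell by 0.89 ± 0.24 (adjusted p = 0.0436; up to 0.111 without control replicate 2 or 3 or heat replicate 1 or 2).

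The photoreceptor genes that passed the test all fell, while genes of light signalling moved in both directions. Besides PHYB, the photoreceptor genes that fell were PHYC by 0.66 (adjusted p = 0.0371), CRY2 by 0.48 (adjusted p = 0.0346), CRY1 by 0.45 (adjusted p = 0.0216) and PHOT1 by 0.36 (adjusted p = 0.0381). Not called were PHYA, PHYD, PHYE, UVR8 and PHOT2, with changes from -0.54 in PHYE (adjusted p = 0.0521) to 0.10 in PHOT2 (adjusted p = 0.816). Of 22 measured genes of photoreceptors and light signalling, 2 rose and 7 fell, or 3 and 9 adjusted over the list alone, with a median of -0.30 (camera adjusted p = 0.114; 0.0435 without control replicate 3). BBX22 (AT1G78600) and HY5 (AT5G11260), which promote light-dependent development, rose by 1.36 ± 0.19 (adjusted p = 0.00398) and 1.2 ± 0.12 (adjusted p = 0.000802). PHYB (AT2G18790), a red light receptor that also senses temperature, fell by 0.90 ± 0.16 (adjusted p = 0.0107). PIF5, a factor that phytochromes repress, fell by 0.92 ± 0.17 (adjusted p = 0.0113). Both of these calls were lost without heat replicate 1 (adjusted p = 0.0504 for PHYB and 0.0524 for PIF5). Both were also lost with the age covariate, with PHYB at -0.54 (adjusted p = 0.501) and PIF5 at -1.39 (adjusted p = 0.0968). PIF4, which promotes growth in warmth, differed by 0.60 ± 0.18 and did not pass (adjusted p = 0.0585); over the alternatives its adjusted p ran from 0.0232, without control replicate 1, to 0.644, after scaling to the Bacillus controls.

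Of 12 light-harvesting antenna genes, 2 rose and 1 fell, or 2 and 3 adjusted over the list alone. The list median was -0.12, its mean 0.57 and its test pointed up without a call (camera adjusted p = 0.885). The members that rose were the early light-induced genes ELIP1 (AT3G22840), with 5.96 ± 0.12 (adjusted p = 7.16e-07), and ELIP2, with 1.81 ± 0.13 (adjusted p = 0.000246); their proteins protect the photosystems under stress and do not form the standing antenna. LHCB5, a minor antenna protein, fell by 0.27 ± 0.07 (adjusted p = 0.0465), a call lost in each of the 6 fits that left out 1 array (up to 0.143). In chlorophyll synthesis 1 of 14 genes rose and 0 fell, also adjusted over the list alone, with a median of 0 (-0.48 after scaling to the Bacillus controls; camera adjusted p = 0.705). The member was the reductase gene DVR, with 0.57 ± 0.13 (adjusted p = 0.0227; up to 0.0872 without control replicate 2 or any heat replicate), which was 0.09 after that scaling (adjusted p = 0.727). In flavonoid and anthocyanin synthesis 1 of 11 rose and 0 fell, also adjusted over the list alone, with a median of 0.12 (-0.36 after that scaling; camera adjusted p = 0.451); the member was the regulator MYB111, with 0.53 ± 0.08 (adjusted p = 0.00618; 0.06 after that scaling, adjusted p = 0.832).

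The circadian clock had 4 rises and 5 falls in 15 genes, or 4 and 6 adjusted over the list alone, with a median of -0.26 and a mean of 0 (camera adjusted p = 0.864). The clock gene LNK1 rose by 2.43 ± 0.17 (adjusted p = 0.000178) and RVE1, which links the clock to auxin, by 1.74 ± 0.21 (adjusted p = 0.00198). The evening repressor TOC1 fell by 1.42 ± 0.21 (adjusted p = 0.0045) and PRR5 by 1.64 ± 0.38 (adjusted p = 0.0261; up to 0.0916 without control replicate 1 or any heat replicate). In auxin synthesis and response 2 of 17 genes rose and 1 fell, also adjusted over the list alone, with a median of 0.13, or -0.35 after scaling to the Bacillus controls (camera adjusted p = 0.556). The auxin response repressor IAA2 fell by 1.07 ± 0.19 (adjusted p = 0.00959). IAA17 rose by 0.94 ± 0.20 (adjusted p = 0.0212; up to 0.0749 without control replicate 2 or any heat replicate), and YUC9 by 0.40 ± 0.11 (adjusted p = 0.0447; up to 0.14 without any 1 array other than control replicate 1), and after scaling to the Bacillus controls IAA17 lay at 0.46 (adjusted p = 0.102) and YUC9 at -0.08. In the cold response list 1 of 8 rose and 1 fell, or 1 and 2 adjusted over the list alone; its median was 0.25 (-0.23 after that scaling), its mean -0.35 and its test up without a call (camera adjusted p = 0.885). The cold acclimation factor CBF2 fell by 2.52 ± 0.57 (adjusted p = 0.0255; up to 0.0974 without control replicate 2 or 3 or heat replicate 1 or 3), and the dehydrin gene COR47 rose by 1.16 ± 0.24 (adjusted p = 0.0173; up to 0.0605 without control replicate 2 or any heat replicate). PRR5, IAA17, YUC9, CBF2 and COR47 were not called with the age covariate. PRR5 was then at -0.73 (adjusted p = 0.721), IAA17 at 1.42 (adjusted p = 0.158) and YUC9 at 0.70 (adjusted p = 0.155). CBF2 was at -3.99 (adjusted p = 0.15) and COR47 at 0.48 (adjusted p = 0.677).

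**Figure D2:**
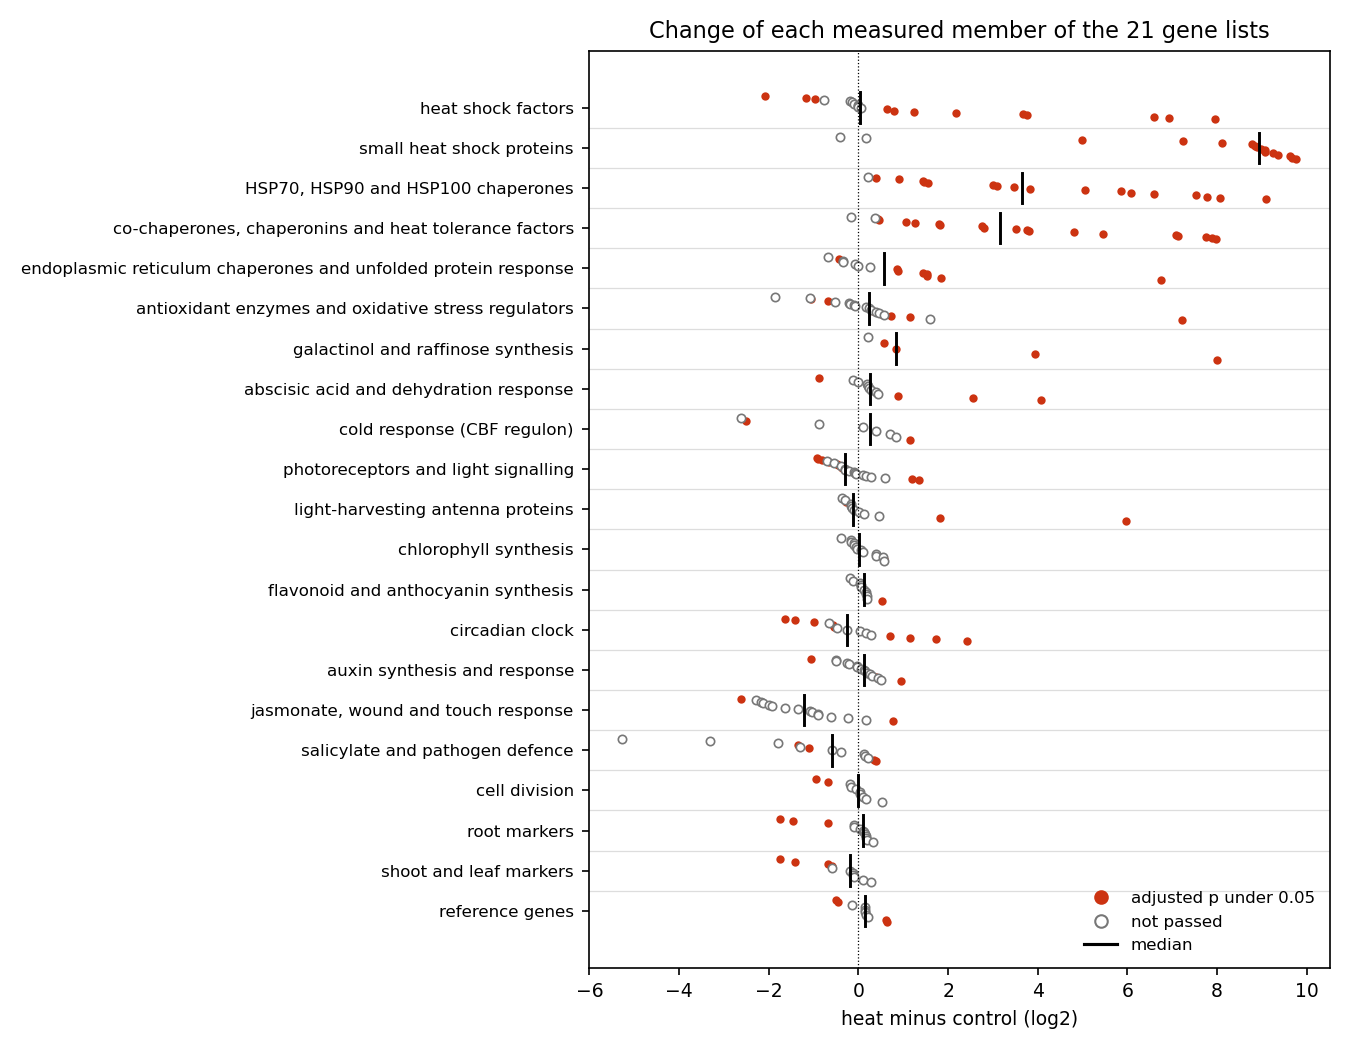
Heat minus control change (log2) of each measured member of the 21 gene lists. Filled points passed at an adjusted p under 0.05 over all probe sets, open points did not, and black bars are list medians. The small heat shock proteins, with a median of 8.94, and the other chaperone lists lie to the right, while the medians of most other lists lie near 0 and several of them cross it after scaling to the Bacillus controls.

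Among genes that passed the test, those with the largest falls included regulators of rapid stress responses. ERF6 fell by 4.74 ± 0.85 (adjusted p = 0.0106), the related factor AT5G51190 by 4.67 ± 0.77 (adjusted p = 0.00737), ERF104 by 3.85 ± 0.66 (adjusted p = 0.00902) and CAF1a, a deadenylase subunit that shortens messenger tails, by 4.58 ± 0.72 (adjusted p = 0.00609). These 4 genes had higher levels in control arrays 2 and 3 than in control array 1, as in ERF6 with 6.67, 9.54 and 10.21 in control arrays 1, 2 and 3, and with the labelled age as a covariate they fell by 7.15, 7.04, 5.45 and 6.66 and were not called (adjusted p = 0.0925, 0.062, 0.113 and 0.0684). The mitochondrial carrier gene UCP5 fell by 3.90 ± 0.80 (adjusted p = 0.0181) and AT4G27280, a calcium-binding protein gene, by 3.77 ± 0.90 (adjusted p = 0.0304); these calls were lost for UCP5 without control replicate 2 or heat replicate 1 or 3 (up to 0.0737), and for AT4G27280 without any 1 array other than control replicate 1 (up to 0.0966). UCP5 and AT4G27280 were at -5.94 (adjusted p = 0.135) and -5.93 (adjusted p = 0.176) with the age covariate. GER1 (AT1G72610), a germin-like cell wall protein gene, fell by 3.79 ± 0.12 (adjusted p = 6.48e-06), the aspartyl protease family gene AT1G09750 by 3.70 ± 0.13 (adjusted p = 9.07e-06) and AT3G19030 by 4.36 ± 0.24 (adjusted p = 6.7e-05). EXPA1 fell by 3.96 ± 0.46 (adjusted p = 0.00187), and by 2.42 with the labelled age as a covariate (adjusted p = 0.193).

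**Figure D3:**
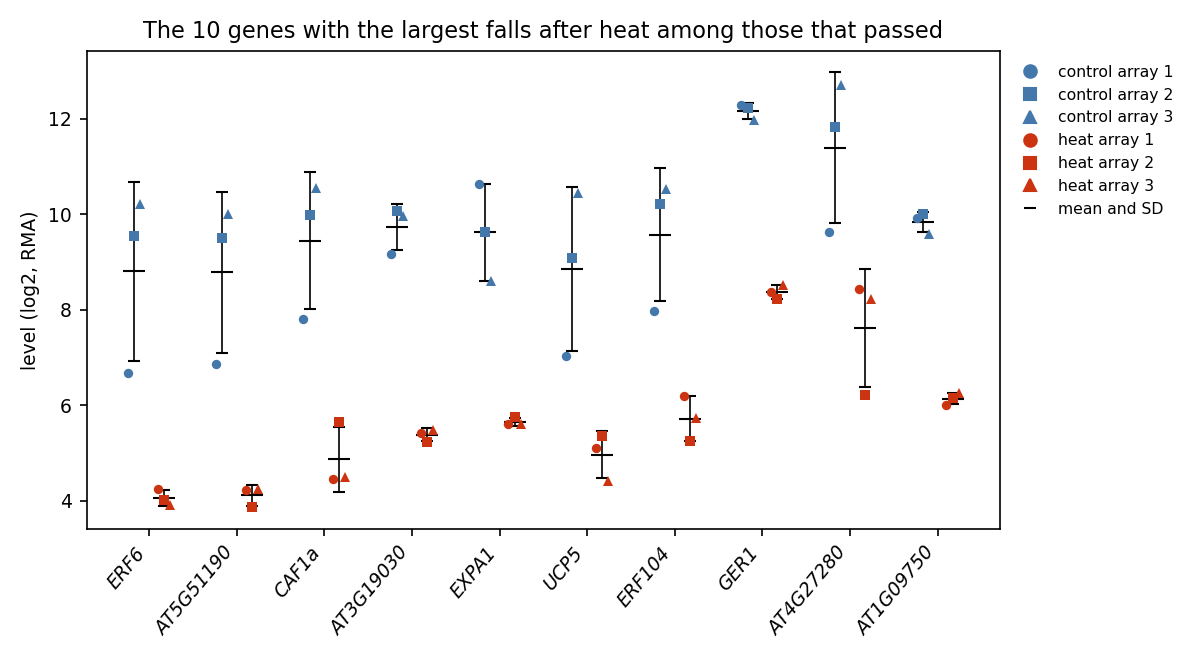
Levels in the 6 arrays of the 10 genes with the largest falls among those that passed the test. The vertical axis is the RMA level on the log2 scale, points are arrays, and black bars give the mean and standard deviation of 3 arrays. All heat arrays lie below all control arrays, and control array 1 lies below the other control arrays for ERF6, AT5G51190, CAF1a, AT3G19030, UCP5, ERF104 and AT4G27280.

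Of 16 jasmonate, wound and touch genes, 1 rose and 1 fell, also adjusted over the list alone. The list median of -1.22 was not called (camera adjusted p = 0.087), and it was called without control replicate 1 (adjusted p = 0.000348). Relative to the control mean of each gene, the list medians were -1.37, -0.30 and 1.62 in control arrays 1, 2 and 3 and -1.37, -1.21 and -1.41 in heat arrays 1, 2 and 3. The jasmonate repressor JAZ6 fell by 2.61 ± 0.53 (adjusted p = 0.0168; up to 0.0679 without any 1 heat replicate), and LOX2, a plastid lipoxygenase gene of jasmonate synthesis, rose by 0.77 ± 0.18 (adjusted p = 0.0269; up to 0.0954 without any 1 heat replicate; 0.29 after scaling to the Bacillus controls, adjusted p = 0.27). Of 13 salicylate and pathogen defence genes, 2 rose and 2 fell, or 2 and 3 adjusted over the list alone, with a median of -0.60 (camera adjusted p = 0.326, or 0.00854 without control replicate 1). The list medians were -0.36, 0.05 and 0.65 in control arrays 1, 2 and 3 and -0.64, -0.35 and -0.81 in heat arrays 1, 2 and 3. The lowest change, -5.27 in WRKY40, was not called (adjusted p = 0.0526), with levels of 5.35, 10.41 and 11.62 in control arrays 1, 2 and 3. The salicylate receptor gene NPR1 fell by 1.36 ± 0.28 (adjusted p = 0.018; up to 0.0709 without control replicate 2 or heat replicate 1 or 3) and PR5 by 1.11 ± 0.23 (adjusted p = 0.0187; up to 0.0763 without heat replicate 1 or 2). The rises were small, 0.38 ± 0.11 in the salicylate synthesis gene ICS1 (adjusted p = 0.0499; up to 0.154 without any 1 array other than control replicate 3) and 0.35 ± 0.09 in the defence marker PR1 (adjusted p = 0.0466; up to 0.13 without any 1 array), and after scaling to the Bacillus controls these genes lay at -0.10 and -0.13. LOX2 and NPR1 were not called with the age covariate, at 1.2 (adjusted p = 0.166) and -2.23 (adjusted p = 0.0911). ICS1 and PR1 were not called with it either, at 0.02 (adjusted p = 0.97) and 0.19 (adjusted p = 0.744).

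Markers of organs and of growth were lower in part. Of 11 shoot and leaf markers, 0 rose and 4 fell, or 1 and 5 adjusted over the list alone, with a median of -0.19 (camera adjusted p = 0.0352; adjusted p = 0.546 with an estimated correlation). The leaf polarity gene AS1 (AT2G37630) fell by 1.76 ± 0.31 (adjusted p = 0.00971), the epidermal cuticle gene FDH by 1.42 ± 0.13 (adjusted p = 0.000697), the meristem gene KNAT1 by 0.68 ± 0.18 (adjusted p = 0.0396; up to 0.132 without any 1 array other than control replicate 2) and the epidermal factor ML1 by 0.58 ± 0.11 (adjusted p = 0.0111; up to 0.0514 without heat replicate 1). The list call was lost without control replicate 2 (adjusted p = 0.0805) and without heat replicate 3 (adjusted p = 0.0551). Of 13 root markers, 0 rose and 3 fell, also adjusted over the list alone; their median was 0.10 (-0.37 after scaling to the Bacillus controls), their mean -0.22 and their test down without a call (camera adjusted p = 0.864). The endodermis factor SCR fell by 1.76 ± 0.13 (adjusted p = 0.000287), the root glucosidase gene PYK10 by 1.45 ± 0.13 (adjusted p = 0.000589) and the aquaporin gene TIP2;3 by 0.67 ± 0.09 (adjusted p = 0.00375). Of 10 cell division genes, 0 rose and 2 fell, also adjusted over the list alone, with a median of -0.02 that was 0.06 after quantile normalization and 0.09 after centring on the array medians (camera adjusted p = 0.705). The cyclin genes CYCD3;1 and CYCA1;1 fell by 0.95 ± 0.21 (adjusted p = 0.0216) and 0.69 ± 0.17 (adjusted p = 0.0308), and both calls were lost without any 1 array other than control replicate 3 (up to 0.0795 and 0.0993). AS1, KNAT1 and CYCD3;1 were not called with the age covariate. They were then at -1.02 (adjusted p = 0.489), -0.25 (adjusted p = 0.809) and -0.43 (adjusted p = 0.694).

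Reference genes, used as internal standards, changed in 4 of 10 cases, with 2 rises and 2 falls, or 3 and 2 adjusted over the list alone. Their median was 0.15, or -0.33 after scaling to the Bacillus controls (camera adjusted p = 0.334). UBQ10 rose by 0.64 ± 0.08 (adjusted p = 0.00264) and GAPC1 by 0.62 ± 0.07 (adjusted p = 0.00207), changes that were 0.16 and 0.14 after that scaling. ACT2 fell by 0.45 ± 0.09 (adjusted p = 0.015; up to 0.0546 without control replicate 2 or heat replicate 1) and SAND by 0.51 ± 0.13 (adjusted p = 0.0375; up to 0.109 without control replicate 1 or 2 or heat replicate 1 or 3), which was -0.12 with the labelled age as a covariate (adjusted p = 0.873). The control probe sets of actin and GAPDH differed along the transcript, with medians of 0.99 at the 5′ end, 0.59 in the middle and 0.31 at the 3′ end, heat minus control. At the 3′ end the actin probe sets were at 0.06 and -0.03, and those of GAPDH at 0.58 and 0.62.

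A run of neighbouring genes on chromosome 2, from AT2G07667 to AT2G07835 in locus order, was singled out after its values were seen. Of its 46 measured genes, 29 rose at least 2-fold and 0 fell, and the median change was 2.19. AT2G07741 rose by 4.71, AT2G07722 by 4.59 and AT2G07675 by 4.41. The names of their probe sets mark sequence shared with other transcripts, so a rise of these genes themselves is not shown. Other genes inside the run did not pass the test. Examples are the transporter gene ABCC13 with 0.06 (adjusted p = 0.672) and the replication licensing gene MCM5 with 0.26 (adjusted p = 0.19). Their probe sets carry no mark of shared sequence. The mark does not separate the genes that rose from the others, however. Over the run, the 33 probe sets with the mark had a median of 2.29 and the 17 without it 1.70. AT2G07777, without the mark, rose by 3.33 (adjusted p = 2.17e-05), and AT2G07713, with it, differed by 0.11 (adjusted p = 0.59). Of the 50 measured genes next to the run, 25 on each side, 0 rose and 2 fell at least 2-fold.

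**Figure D4:**
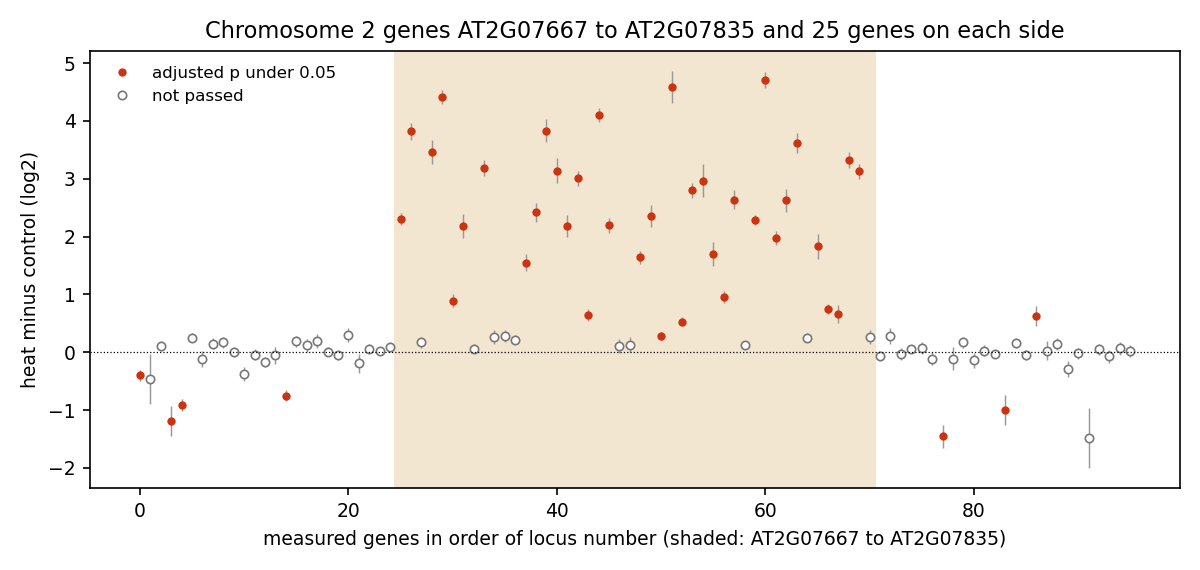
Heat minus control change (log2, with standard error) of measured chromosome 2 genes in order of locus number. The shaded run holds 46 genes, with 25 genes on each side; filled points passed at an adjusted p under 0.05 and open points did not. Changes reach 4.71 inside the run, where several genes such as MCM5 lie near 0. Many probe sets of the run are named as sharing sequence, so their points may report transcripts from elsewhere.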

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

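The tests of the control probe sets in this part were chosen after their values had been seen. Bacillus control RNAs are added to the sample RNA before labelling and have no plant target. The median over their 24 probe sets was higher in all heat arrays than in all control arrays, by 0.49 ± 0.15 (log2, ± SE, n = 3 each), a signal in probe sets that the comparison of plant genes leaves out. If all added control RNAs had shifted alike, the hybridization controls, which are added after labelling, would have moved as much. They moved by 0.07 ± 0.20, and the Bacillus controls exceeded them by 0.42 ± 0.28, which is within 2 standard errors, so this explanation stays open. Less messenger RNA per total RNA after heat, which would be a biological effect of the heat group, cannot be told apart from more control RNA added to the heat samples, since either would put each heat array above each control array, as measured (the lowest heat array lay 0.17 above the highest control array), and the difference runs with the groups.

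The probe set for Arabidopsis 25S ribosomal RNA was higher by 0.75 ± 0.11 in the heat arrays, each of which lay above each control array. The median of the 5′ actin and GAPDH probe sets was higher by 0.99 ± 0.10, that of the middle probe sets by 0.59 ± 0.09 and that of the 3′ probe sets by 0.31 ± 0.07. For each of these medians, each heat array lay above each control array. The 3′ median joins actin probe sets at 0.06 and -0.03, neither called, with GAPDH probe sets at 0.58 and 0.62. The cause of the difference along the transcript was not tested. The median of the 5 ubiquitin control probe sets was higher by 0.69 ± 0.08, again with no overlap between the groups.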

How the results depend on the processing

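Of the alternatives, the scaling to the Bacillus controls and the tests with the spread of each probe set alone were chosen after seeing the data; the cause was not tested for any of the changes given here unless stated. Of 357 list results over 17 alternatives, 323 kept their side of the threshold, 16 of them with the other direction and no call, and the 323 include every result of the HSP70, HSP90 and HSP100 chaperones (adjusted p from 1.17e-64 to 0.0424) and of the co-chaperones (from 2.81e-57 to 0.0424). Of 1319 results over 15 alternatives for 88 named genes, 1121 kept their side of the threshold, 190 lost and 5 gained a call and 3 called values changed sign; among the 1121, 8 uncalled values of HSFA1A and HSFA1B changed sign. Of the 85 called genes, 30 were called under all 15, and 26 also with their own spread, before and after the Bacillus scaling; own spread alone ended 34 calls and own spread after that scaling 43. The called values that changed sign, YUC9 (-0.08), ICS1 (-0.10) and PR1 (-0.13), followed from the Bacillus scaling, which moved the median of all probe sets to -0.46. The higher and lower counts were 359 and 227 with the labelled age as a covariate, which is collinear with heat in part and ended 54 calls on named genes. By construction they were 1778 and 2614 with no minimum fold and 317 and 182 with a minimum log2 change of 2. With the Bacillus scaling 2906 were lower, in a fit with 68.8 prior degrees of freedom whose p-values, those of lists among them, are therefore too small for genes that vary much. With the spread of each probe set alone the counts were 325 and 1205 after that scaling and 541 and 551 without it. Other counts were within 1.5 times the reported ones.

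Calls lost with an estimated correlation were heat shock factors and galactinol (both 0.451), small heat shock proteins (0.0573), and endoplasmic reticulum chaperones and shoot markers (both 0.546). Heat shock factors were not called after median centring (0.107) or with age (0.155), and ran from 0.00455 to 0.101 (without control replicate 1) with 1 array left out. Shoot markers were not called with quantile normalization (0.0566), without the dimmest probe sets (0.0801), with age (0.259) or with the Bacillus scaling (0.0586), and ran from 0.0191 to 0.0805 with 1 array left out, with the call lost without control replicate 2 (0.0805) or heat replicate 3 (0.0551). Calls gained with fry, which does not compare with other genes, were antioxidants (0.00117), antenna proteins (0.015), reference genes (0.0312), and abscisic acid and root markers (both 0.0496). Gained with the Bacillus scaling were antioxidants (0.0348) and abscisic acid (0.00218), pointing up, and salicylate (0.0348) and jasmonate (0.0043), pointing down. The upward calls are relative to other genes. The medians of these 2 lists were then -0.24 and -0.22, and that of all probe sets was -0.46. Abscisic acid was also called with quantile normalization (0.0354), jasmonate with centring (0.017) and age (2.4e-06), and salicylate with age (0.00124). With 1 array left out, the ranges were 0.00704 to 0.157 for abscisic acid, called without control replicate 2 (0.00704) or heat replicate 1 (0.0208), and 0.0435 to 0.214 for light signalling, called without control replicate 3. They were 0.000348 to 0.545 for jasmonate and 0.00854 to 0.681 for salicylate, both called without control replicate 1.

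Same-numbered arrays did not deviate alike: their deviations correlated across probe sets at r = 0.04, 0.19 and -0.08. Weak correlations cannot show whether the samples were paired in the experiment. With the replicate block, abscisic acid and jasmonate were called (both 0.0468), and AT4G27280, CSD2, LHCB5, DVR, YUC9, PR1, CYCA1;1, KNAT1 and ACT2 were not (from 0.0516 to 0.101). Of the 10 ways to split the 6 arrays into groups of 3, 1 gave as many probe sets past the threshold as the real split, the real split itself with 1543, and the highest other gave 0; 10 splits are too few for a share under 0.05. Probe sets at levels near 3 to 4 lie close to the lowest values of the arrays, where background limits what differences can be seen.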

Other observations

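The tests in this part were chosen after the results were seen, including the scan of words in gene titles, and none of the 27 words called among 411 kept its call with an estimated correlation. Genes with the title word 3-ketoacyl-CoA are mostly synthases that elongate the fatty acids of cuticular wax, and include the thiolase genes PKT3 and PKT4. Of these 20 genes 12 fell and 0 rose, with a median of -0.87 (camera adjusted p = 0.000614; adjusted p = 0.826 with an estimated correlation). PKT3 and PKT4 differed by -0.10 and 0.42 and were not called, while KCS1 fell by 2.53, KCS8 fell by 2.51 and KCS20 fell by 2.42. The galacturonosyltransferases, which build pectin and other wall polymers, fell in 8 of 13 genes and rose in 1, with a median of -0.54 (camera adjusted p = 0.00182; adjusted p = 0.826 with an estimated correlation); GAUT9 fell by 1.19 and GAUT7 by 1.06, while GAUT12, which acts in xylan synthesis, rose by 1.72. The 1,3-beta-glucan synthases, which deposit callose, fell in 7 of 12 genes and rose in 0, with a median of -0.62 (camera adjusted p = 0.028; adjusted p = 0.826 with an estimated correlation), as in GSL8, which fell by 1.17, and GSL05, which fell by 1.15.

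Subunits of the core proteasome, which degrades damaged proteins and shares the title word threonine-type, rose in 7 of 18 genes and fell in 0, with a median of 0.31 that was -0.17 after scaling to the Bacillus controls (camera adjusted p = 0.000724; adjusted p = 0.83 with an estimated correlation). PBC2 rose by 1.01 and PBB2 by 0.61. After that scaling they were at 0.53 (adjusted p = 0.0634) and 0.13 (adjusted p = 0.607) and were not called. Genes with ethylene in their titles fell in 10 of 19 cases and rose in 0, with a median of -0.49 (camera adjusted p = 0.000614; adjusted p = 0.826 with an estimated correlation). Of the 27 words, 8 pointed up and 19 down, and the medians of 6 of the 8 were below 0 after scaling to the Bacillus controls; the other upward words, heat and shock, gave the same counts. The 39 genes with auxin in their titles had 3 rises and 14 falls and a median of -0.38 (camera adjusted p = 0.00294; adjusted p = 0.826 with an estimated correlation), where the auxin list had a median of 0.13. The 23 with photosystem had 0 rises and 6 falls and a median of -0.23 (camera adjusted p = 0.0139; adjusted p = 0.826 with an estimated correlation), where the antenna list had a median of -0.12 and a mean of 0.57. GAUT7, GAUT12, GSL05, PBC2 and PBB2 were not called with the labelled age as a covariate (adjusted p = 0.37, 0.0874, 0.107, 0.0584 and 0.269). Titles were present for 7161 of 20310 genes, so most genes took no part in this scan.

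Many heat genes and wound genes had higher levels in control array 3 than in the other control arrays. A common share of RNA from heated seedlings in that array is argued against, since 18 of the 47 probe sets that rose at least 64-fold lay over 1 log2 unit from the level that the median share predicts. It would not raise the jasmonate, wound and touch genes either, whose median was 3.06 higher in control array 3 than in control array 1 but only 0.24 higher in the heat arrays. A heat array with a wrong label is argued against by the small heat shock proteins, which lay 0.38 above the other control arrays in control array 3 and at least 8.97 above them in each heat array. A brief stress to those seedlings before sampling may have raised these genes, a hypothesis that was not tested. The labelled age differs between the control arrays and stays open as well. It follows the order of the arrays, however, and conflicts with the single age in the series text.

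The chromosome 2 genes from AT2G07667 to AT2G07835 rose by a median of 2.19. Of the 1266 probe sets with no named gene, 31 rose at least 2-fold, by up to 6.24, while 0 fell. Among all 22746 tested probe sets 637 rose and 906 fell by as much. The share of unnamed probe sets that rose was thus near that of all probe sets. With 0 falls among them, however, their changes of that size all went up, unlike those of all probe sets. A rise of all probe sets of that level is argued against, since the 8849 other probe sets in the same range of control levels had a median of 0.04 and a 95th percentile of 0.44. The shift of the Bacillus controls, 0.49, was smaller than the median rise of the run. After scaling to them the median of the run was 1.71. That scaling takes the same amount from all probe sets of an array, so this value was fixed by the shift and is no separate test. The region is known to carry a copy of most of the mitochondrial genome, so these probe sets could report mitochondrial transcripts. The 33 probe sets whose names mark shared sequence had a median of 2.29 and the 17 others 1.70, and because those names mark sharing within the array design only, a rise of the chromosome 2 genes and of transcripts from elsewhere cannot be told apart.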
